A study of Mus musculus with 7 samples.

How the data were processed

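Fetal cells were identified by a paternally inherited green fluorescent protein transgene and sorted, as fluorescent cells that excluded propidium iodide, from the lungs of pregnant C57BL/6J mice, per the labels' protocols. The same protocols give females of 10 to 12 weeks, sorting into lysis buffer at 10 to 40 cells per microlitre, frozen storage for 1 to 8 days, and whole-transcript amplification of RNA from up to 80 cells before biotin labelling and hybridisation. Lysates are described for each female, so the 7 arrays were taken as 7 separate animals; the exact number of cells behind each array is not given in the sources used here.

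The values used were log2 signals deposited by the authors for 45101 probe sets on 7 arrays. The MAS5 algorithm is named, without a version, in the submitters' processing notes; background correction, scaling target and any normalization between arrays are not given in the sources used here. The log base was inferred from the values, which run from -0.53 to 14.36: in base e or base 10 the highest would exceed the range of a 16 bit scanner. Array medians were close but not equal. Detection calls were not used here, so the depth of an array is expressed as its signal over the receptor genes. There were 0 missing values. Without the normalization step, differences between arrays in overall brightness cannot be separated from how the authors scaled them. Quantile normalization was therefore an alternative for the list tests, list scores, pairwise correlations within lists and the trend. It was not applied to the counts above background, the counts of genes highest on an array or the correlations between list scores.

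Gene names came from the platform annotation supplied with the probe sets: 34958 probe sets have 1 symbol, 932 have several and 9211 are not listed. Only probe sets with 1 symbol were named. Symbols were compared with the RefSeq annotation of the mouse assembly GRCm38.p6 through Entrez identifiers (34754 probe sets matched, 0 symbols changed), and no coordinates were used because the build behind the probe annotation is not given. A gene with several probe sets was represented by the one with the highest mean signal, giving 18194 genes. Genes without a probe set of their own symbol, among them 44 of the 505 list entries, were not analysed here.

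Before the data were examined, 32 gene lists, the tests and the rule for naming genes were fixed. Lists covered trophoblast hormone and trophoblast labyrinth and regulator genes, T cell, NK cell, B cell, monocyte and macrophage, alveolar macrophage, granulocyte, mast cell with basophil and eosinophil, erythroid, platelet and progenitor genes, MHC class I and II, endothelial, fibroblast and matrix, mesenchymal stem cell surface, smooth muscle, lung and general epithelium, hepatocyte and visceral endoderm, neural, cardiac and skeletal muscle, pluripotency, cell cycle, imprinted, immediate early and heat shock, interferon, chemokine and adhesion, angiogenic, Y-linked and housekeeping genes. The lists hold 461 measured entries for 459 different genes. Named genes were, for each list, up to 4 members with the highest mean among those above background on at least 6 arrays or otherwise the member above on most arrays; the 15 highest means; the 15 largest SDs among genes above background on at least 3 arrays; every measured Y-linked gene and Xist; and the 10 smallest p-values of the trend where fewer than 5 genes passed. Genes named outside that rule were chosen after their values were seen. They are Fos, Hspa1a and Hsph1 in the trend, and Hbb-b2 and Hba-a2 beside the erythroid list. Others are the labyrinth genes listed by their highest array and those of the closing observations.

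A gene was above background on an array when its signal exceeded the 95th percentile of 83 receptor probe sets (74 genes) on that array. With so few probe sets the threshold rests on about 4 values per array. For each list, the median of its genes minus the median of the receptor genes was tested over the 7 arrays with an exact two-sided sign-flip permutation test, adjusted by Benjamini-Hochberg over the lists, and its mean was ranked among 10000 random lists of the same size. The trend used limma (lmFit, eBayes with trend) on embryonic day as a number, with Benjamini-Hochberg adjustment and a threshold of 0.05; lists with at least 3 genes in that fit were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Variation between arrays was described by list scores, Dixon's criterion for 7 values (0.568) and mean pairwise correlations set against 10000 random lists drawn within 100 ranks of mean signal.

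The limma trend, the sign-flip test, Dixon's criterion and the pairwise correlations were tested on simulated data; the background threshold, camera and fry were not. With slopes of 1, 2 and 4 log2 units per day added to 200 of 4020 genes at the real spread between arrays, the limma trend recovered 15.22%, 65.37% and 92.12% of them, with 4.66% of calls false. In that setting slopes of about 1 unit per day or less were mostly missed. Many planted genes ease the adjusted threshold, so the limit is optimistic for the real data. There, slopes of -2.19 for Tbcb and -2.06 for Prxl2c had adjusted p-values of 0.407 and 0.681 (limma). For list tests on 7 arrays, the sign-flip test called 5.35% of simulations without an effect and 88.8% of those with a shift of 1.5 SD. Dixon's criterion was exceeded by 4.7% of simulated sets.

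Alternatives fixed in advance were the 99th percentile of the receptor probe sets, the 40th percentile of all probe sets as threshold, the median over a gene's probe sets, quantile normalization, signals floored at the threshold, no filter or a filter on all 7 arrays, a contrast of day 17.5 with day 14, 2 classes of days, array weights, a covariate, single probe sets, and leaving out each array. After seeing that thresholds differed between arrays, a 90th percentile threshold and a single pooled threshold (6.17) were added. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.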

Results

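Gene expression was profiled in fetal cells recovered from the lungs of pregnant mice. Wild-type C57BL/6J females had been mated to males homozygous for an enhanced green fluorescent protein transgene, so every fetus carried the green label and the mother did not. Live green cells were sorted from the maternal lungs of each female, up to 80 cells were used per amplification, and the amplified cDNA was hybridised to 1 array per sample. The 7 arrays form a single group of replicates that differ in the embryonic day of the pups: 2 arrays at E14, 1 at E15, 1 at E16 and 3 at E17.5. Arrays 4 and 5 are the E14 samples, array 6 is E15, array 3 is E16, and arrays 1, 2 and 7 are E17.5. The design holds no group of maternal lung cells or of other fetal cells, so the questions it poses are which genes were measured above background, in how many of the 7 samples, and whether their levels followed gestational age.

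The deposited values were log2 signals for 45101 probe sets, with array medians between 3.12 and 3.43. Pearson correlations over all probe sets, which are across probe sets within pairs of arrays and not across samples, lay between 0.361 and 0.529 in the 21 pairs, with a median of 0.429. No 2 arrays held identical values. The background threshold of an array was the 95th percentile of 83 probe sets for olfactory, vomeronasal and taste receptors, sensory genes with little expected transcription in these cells. It was 8.97 on array 1, 5.59 on array 2, 4.85 on array 3, 5.74 on array 4, 4.77 on array 5, 5.76 on array 6 and 6.93 on array 7. Of 18194 named genes, 432 exceeded it on array 1, 3612 on array 2, 5828 on array 3, 3900 on array 4, 6632 on array 5, 3641 on array 6 and 2132 on array 7. These counts depended strongly on the thresholds. On array 1 the threshold lay above the 95th percentile of all its probe sets (7.41). A single pooled threshold (6.17), chosen after seeing the data, gave a far narrower range. In array order its counts were 2728, 2369, 2512, 3019, 3414, 2803 and 3167. The number of arrays limits the precision of every value below, which is a mean ± SD of the log2 signal over n = 7 arrays unless stated otherwise.

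A small core of genes was above background in every sample. The highest mean signals belonged to AY036118 (13.54 ± 0.16), the RNA-binding protein gene Hnrnpab (13.49 ± 0.20), the nuclear non-coding RNA Malat1 (13.19 ± 0.84), beta-actin (Actb, 12.90 ± 0.20), the mitochondrial gene ND5 (12.86 ± 0.31) and the ferritin heavy chain gene Fth1 (12.71 ± 0.37). The next were Gm6958, the ribosomal protein gene Rpl13a, the alveolar surfactant gene Sftpc (12.68 ± 0.44), the tubulin gene Tuba1a, the chromatin protein gene Hmgn1, the lysozyme gene Lyz1 (12.30 ± 1.28), Ahnak, beta-catenin (Ctnnb1) and gelsolin (Gsn). In all, 117 genes (0.643%) were above background on all 7 arrays, 427 on at least 6 and 4020 on at least 3, whereas 6864 were above on none. Of 74 receptor genes, 3 were above on at least 3 arrays and 0 on at least 6. The counts depend on the threshold and on single arrays: 57 genes were above on all 7 arrays at the 99th percentile of the receptor probe sets, 5373 at the 40th percentile of all probe sets, and 40 with the median over a gene's probe sets in place of its brightest one. Without array 1, whose threshold was the highest, 348 genes were above on all remaining arrays; on all remaining arrays but at most 1 there were 1123 without array 1 and 829 without array 7, and on at least 3 there were 2676 without array 5. Probe sets of a gene often differed: of 25 named genes that were above on at least 6 arrays and have several probe sets, the second brightest also reached 6 arrays in 10. For Hnrnpab the second probe set averaged 7.05, for Fth1 6.41, for Ahnak 5.70 and for Ctnnb1 4.89.

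Transcripts of lung epithelium were present in all samples. Sftpc, which encodes surfactant protein C of alveolar type II cells, Scgb1a1, the club cell secretoglobin (11.60 ± 1.05), and Sftpa1, surfactant protein A (10.09 ± 1.07), were above background on 7 of 7 arrays. The phosphate transporter gene Slc34a2 (10.17 ± 1.71) was above on 6. Of 19 measured lung epithelium genes, 7 were above background on at least 6 arrays and 6 more on 3 to 5. The list median lay 3.82 ± 1.38 above the receptor genes, higher on 7 of 7 arrays (exact sign-flip permutation test, two-sided, p = 0.0156, adjusted p = 0.0217), and at the 100th percentile of random lists. The general epithelium list lay 2.26 ± 0.83 above the receptor genes, at percentile 95.09, and 1 of its 12 genes, the keratin gene Krt18 (7.05 ± 1.94), reached 6 arrays.

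**Figure D1:**
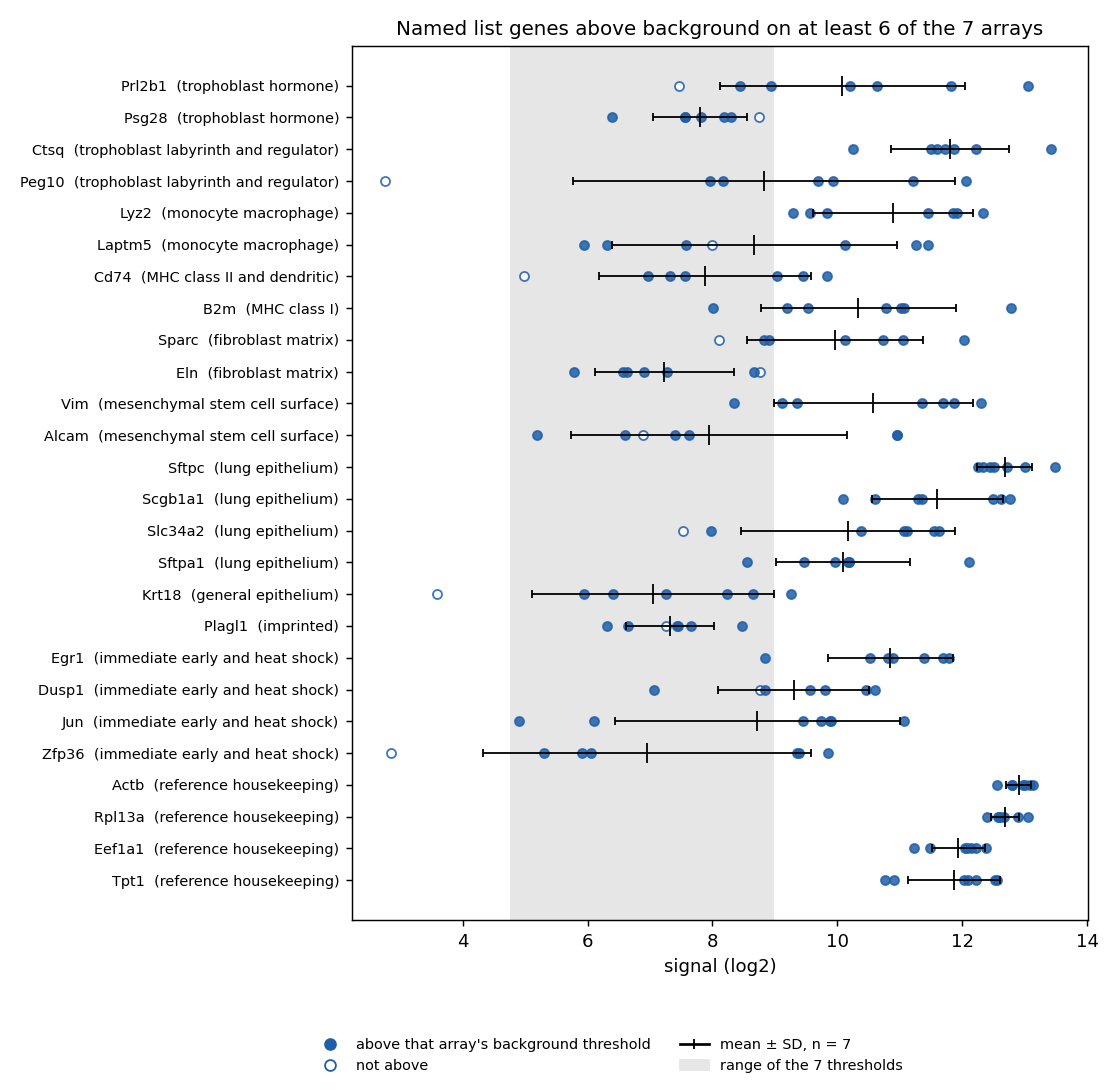
Signal (log2, horizontal axis) on each of the 7 arrays for the up to 4 brightest members of each gene list that were above background on at least 6 arrays. Each circle is 1 array, filled where it exceeds that array's background threshold; the black tick and bar are the mean ± SD (n = 7), and the grey band spans the 7 thresholds (4.77 to 8.97). Sftpc, Actb and Rpl13a lie above 12 on every array, and Peg10, Zfp36 and Jun span more than 6 log2 units.

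Trophoblast genes were a further tissue-restricted group with a few members above background on at least 6 arrays. Ctsq, a placental cathepsin, averaged 11.80 ± 0.95 and was above on 7 of 7 arrays. Peg10, a paternally expressed retrotransposon-derived gene of placenta, averaged 8.83 ± 3.06 and was above on 6. Among the hormone genes of the placenta, the prolactin family member Prl2b1 (10.08 ± 1.96) and the pregnancy-specific glycoprotein gene Psg28 (7.80 ± 0.75) were each above on 6. Of 18 labyrinth and regulator genes, 2 were above on at least 6 arrays and 6 on 3 to 5, and the list lay 2.22 ± 0.96 above the receptor genes on 7 of 7 arrays, at percentile 97.31. Of 22 measured hormone genes, 2 were above on at least 6 arrays, 3 on 3 to 5 and 9 on none. The hormone list lay 0.80 ± 0.52 above the receptor genes, at percentile 4.59 of random lists. The imprinted gene list lay 2.30 ± 0.87 above the receptor genes at percentile 97.82 (0.88 with the median over a gene's probe sets), with 1 of 16 genes, the zinc finger gene Plagl1 (7.32 ± 0.70), above background on at least 6 arrays.

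Blood and immune genes, like most trophoblast genes, were mostly above background in some samples only or in none. Lysozyme 2 (Lyz2), abundant in macrophages, averaged 10.89 ± 1.28 and was above on 7 of 7 arrays, as was beta-2-microglobulin (B2m, 10.34 ± 1.56), the light chain of MHC class I. The lysosomal membrane gene Laptm5 (8.67 ± 2.28) and the MHC class II chaperone Cd74 (7.88 ± 1.69) were above on 6. Members above background on at least 6 arrays numbered 2 of 22 in the monocyte and macrophage list, 1 of 14 in the MHC class II and dendritic list and 1 of 12 in the MHC class I list. There were 0 such members among 17 T cell, 14 B cell, 12 NK cell, 15 granulocyte, 13 erythroid, 10 megakaryocyte and platelet, 10 alveolar macrophage, 12 mast cell, basophil and eosinophil and 15 hematopoietic progenitor genes. Of all 18194 named genes only 427 were above on at least 6 arrays. A count of 0 in lists this short is therefore near that share and does not set these lists apart. The most widely detected member, with ties broken by the higher mean signal, was Zap70 for T cells (5 of 7 arrays), Vpreb3 for B cells (5), Gzma for NK cells (2), the calprotectin gene S100a9 for granulocytes (4), Car2 for the erythroid list (3), Clec1b for platelets (2), Chil3 for alveolar macrophages (3), Cma1 for mast cells (3) and Gata2 for progenitors (4). Ties included Ly6d for B cells, Ccl5 for NK cells and Fabp4 for alveolar macrophages. The erythroid list did not hold the adult globin genes Hbb-b2 and Hba-a2, which were above background on 6 and 5 arrays. Its counts therefore understate how widely red cell transcripts were detected. List medians lay above the receptor genes by 2.37 ± 0.52 for MHC class I, 2.31 ± 1.35 for alveolar macrophages, 2.25 ± 0.45 for B cells, 2.09 ± 0.57 for MHC class II, 1.90 ± 0.51 for monocytes and macrophages and 1.69 ± 0.88 for progenitors. The corresponding values were 1.38 ± 0.51 for platelets, 1.31 ± 0.47 for T cells, 1.14 ± 1.06 for the erythroid list and 0.48 ± 0.46 for NK cells, at percentiles of random lists from 2.91 (NK cells) to 96.67 (MHC class I). With the median over probe sets the NK cell call was lost (0.37, adjusted p = 0.133), and the differences were 1.26 for B cells, 1.06 for progenitors, 0.81 for T cells and 0.48 for the erythroid list. The granulocyte difference (1.14 ± 1.28, exact sign-flip permutation test, adjusted p = 0.0667, higher on 5 of 7 arrays; 0.76 without array 5; 1.19 and adjusted p = 0.0385 with the median over probe sets) and the mast cell list difference (0.55 ± 0.90, exact permutation adjusted p = 0.177, 5 of 7; 0.35 without array 3) did not pass.

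Stromal and vascular genes formed a further group. The matrix protein gene Sparc (9.97 ± 1.41) and elastin (Eln, 7.23 ± 1.11) were above background on 6 arrays, as was the adhesion molecule gene Alcam (7.94 ± 2.20), and the intermediate filament gene Vim (10.57 ± 1.59) was above on 7. The endothelial list lay 3.18 ± 0.70 above the receptor genes, at the 100th percentile of random lists; 8 of its 17 genes were above background on 3 to 5 arrays and 0 on at least 6 (2 with the pooled threshold), with the angiopoietin receptor gene Tek (8.12 ± 2.16) on 5. The mesenchymal stem cell surface list lay 2.55 ± 1.00 above at percentile 98.58 (1.25 with the median over probe sets), and the fibroblast and matrix list 2.39 ± 0.87 above at percentile 99.3. The smooth muscle list did not pass (0.27 ± 0.76, exact sign-flip permutation test, adjusted p = 0.375, higher on 5 of 7 arrays; 0.16 to 0.45 with 1 array left out), and its best detected member was the kinase gene Mylk, above on 5 arrays.

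Stress-responsive and housekeeping genes were prominent. The immediate early transcription factor genes Egr1 (10.85 ± 1.00) and Jun (8.72 ± 2.28) were above background on 7 of 7 arrays, and the phosphatase gene Dusp1 (9.30 ± 1.22) and the mRNA decay factor Zfp36 (6.96 ± 2.63) on 6. Jun was close to the threshold on array 5 (4.90 against 4.77), and its second probe set (5.21) was above on 2 arrays. The immediate early and heat shock list lay 3.53 ± 1.18 above the receptor genes, at the 100th percentile, with 4 of 16 genes above background on at least 6 arrays. The housekeeping list lay 7.70 ± 1.46 above, at the 100th percentile, with 8 of 12 genes on at least 6 arrays, including the elongation factor gene Eef1a1 (11.94 ± 0.42) and Tpt1 (11.87 ± 0.74); the other probe set of Tpt1 averaged 1.13. The cell cycle list lay 2.26 ± 1.01 above the receptor genes at percentile 98.05, with 0 of 19 genes on at least 6 arrays and the replication gene Mcm3 on 5. The chemokine and adhesion list (1.90 ± 0.67, with Cd47 above background on 5 arrays), the angiogenic factor list (1.68 ± 0.34, Pdgfa on 4) and the interferon list (1.38 ± 0.78, Ifit3 on 5) had 0 members on at least 6 arrays. So did the hepatocyte and visceral endoderm list (1.33 ± 0.97, Apom on 4), the pluripotency list (1.29 ± 0.73, Utf1 on 4), the neural list (1.24 ± 0.63, Pax6 on 5) and the cardiac and skeletal muscle list (0.92 ± 0.84, Mb on 5). With the median over probe sets the call was lost for the hepatocyte (0.91, adjusted p = 0.0556), pluripotency (0.82, adjusted p = 0.0714) and neural (0.34, adjusted p = 0.103) lists. The housekeeping difference was then 5.10 and the angiogenic one 0.99.

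**Figure D2:**
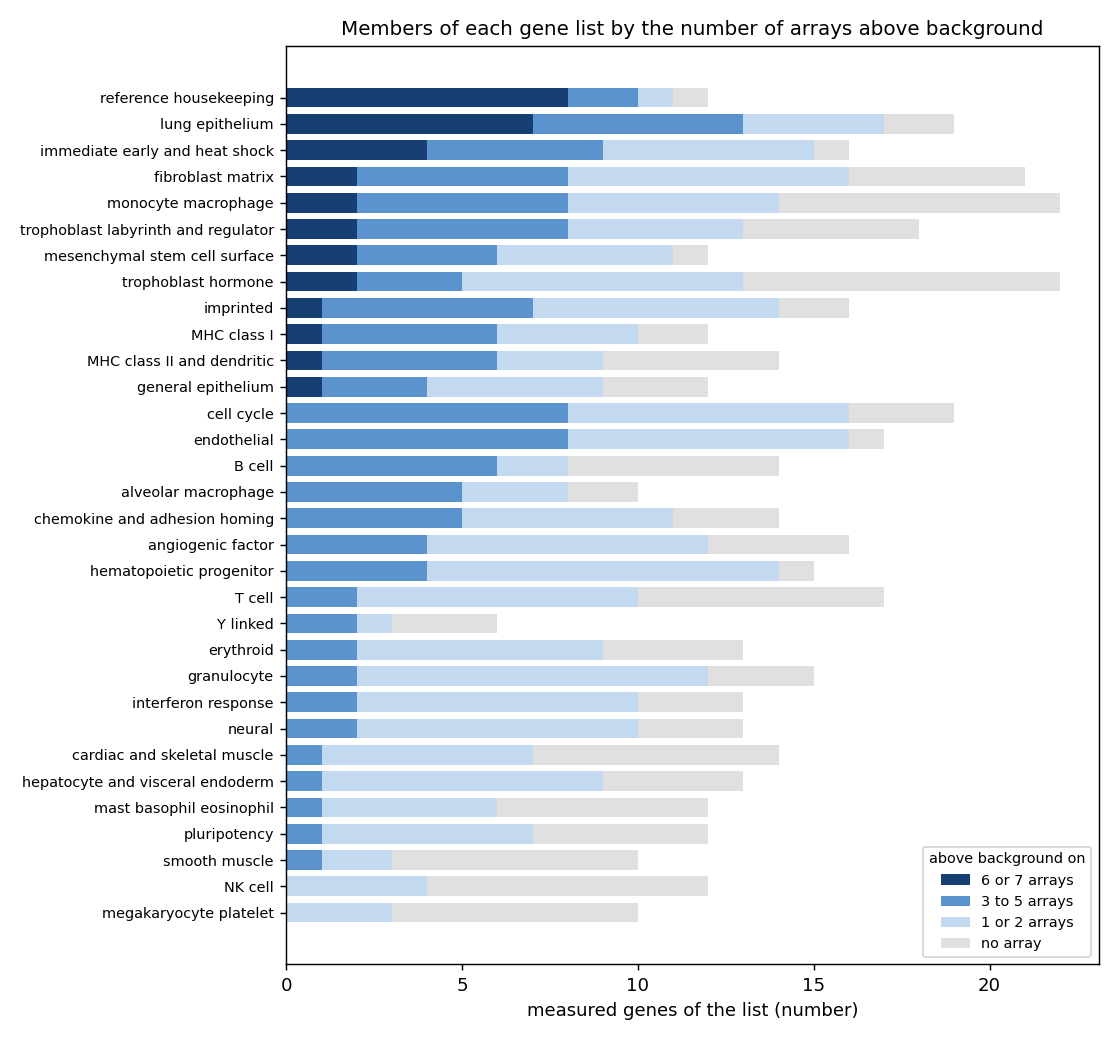
Number of measured genes (horizontal axis) of each of the 32 gene lists that were above background on 6 or 7, 3 to 5, 1 or 2, or no arrays. The housekeeping list has 8 of 12 genes in the darkest class, the lung epithelium list 7 of 19, and the NK cell and platelet lists have 0 genes above background on 3 or more arrays.

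Over the 32 lists, 29 passed against the receptor genes (exact two-sided sign-flip permutation test, adjusted p = 0.0217 or 0.0345), 23 of them on 7 of 7 arrays at an exact p = 0.0156, the smallest p that 7 arrays allow. Different probes are compared, and fixed differences in their affinity repeat on every array, so a pass shows a consistent sign and not that a list was expressed. List genes also had the brightest of their probe sets, a choice that 83 probe sets for 74 receptor genes rarely offer. The median of all named genes itself lay 1.43 ± 0.30 above the receptor genes. Against random lists of the same size, 12 of the 32 lists exceeded the 95th percentile.

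Genes of the sex chromosomes were examined because some of the fetal cells should be male and all maternal cells are female. Eif2s3y (3.68 ± 0.99), Kdm5d (3.97 ± 0.80) and Uty (3.38 ± 1.05), which are expressed widely in male tissues, were above background on 0 of 7 arrays, although a second, dimmer probe set of Eif2s3y was above on 1. Usp9y (3.75 ± 2.06) was above on 1, Zfy2 (5.73 ± 0.85) on 3 and the sex-determining gene Sry (6.92 ± 0.89) on 5. The second probe set of Sry (6.09) was above on 3. The brightest one of Sry is of a type that can hybridise to related sequences. The brightest probe set was of that type in 9 of 40 named genes on at least 6 arrays: Sftpc, Vim, Laptm5, Rpl13a, Gm6958, Tuba1a, Hmgn1, Lyz1 and Gsn. The second probe set of Laptm5 (5.44) reached 3 arrays. Xist, the RNA expressed from the inactive X chromosome of females, was above background on 7 of 7 arrays (8.24 ± 1.83) in 1 of its 3 probe sets, and the next brightest reached 1 array. The Y-linked list of 6 measured genes lay 1.77 ± 0.70 above the receptor genes (0.89 with the median over probe sets), at percentile 68.51 of random lists.

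The slope on embryonic day asked whether expression changed as pregnancy advanced, and 0 of 4020 genes passed (limma, smallest adjusted p = 0.407). The smallest p belonged to Tbcb, a tubulin folding cofactor gene, with a slope of -2.19 ± 0.39 (SE) log2 units per day. Similar slopes that did not pass were those of the diacylglycerol kinase gene Dgkz (-1.89 ± 0.34), serglycin (Srgn, a granule proteoglycan of blood cells, -1.94 ± 0.35), the histone demethylase gene Kdm1a (-1.75 ± 0.32) and the flippase subunit gene Tmem30a (-1.74 ± 0.32). The cell cycle phosphatase gene Cdc25a, Dnajc2, Map4k4, Prxl2c and the ATP synthase gene Atp5e completed the 10 smallest p-values, with slopes from -1.49 to -2.06. With signals under the background threshold set to it, these slopes were smaller: -0.48 for Tbcb, -0.74 for Dgkz, -0.40 for Srgn, -0.28 for Kdm1a and -0.26 for Tmem30a. Tbcb, Srgn, Kdm1a, Tmem30a, Cdc25a and Atp5e were above background on 3 arrays, namely arrays 4, 5 and 6 (E14 and E15). The filter thus admitted them through early arrays where they were high, which favours negative slopes. At an unadjusted p under 0.05 there were 214 genes, 195 with a negative and 19 with a positive slope. That split depended on the processing. After quantile normalization it was 129 against 30, and without a filter it was 621 against 371 among 18194 genes. With signals under the background threshold set to it, the split was 9 against 150. That floor differed with day, being highest on arrays 1 (8.97) and 7 (6.93), both E17.5. It lifts low signals most on those arrays and so pushes slopes upward. The floored split and slopes therefore cannot decide whether genes fell with day. Without array 7, 354 genes had an unadjusted p under 0.05 and 0 passed. The median slope of all tested genes was -0.11 per day. The share of genes above the array's own threshold had a Spearman rho of -0.82 with embryonic day (exact permutation p = 0.033, adjusted p = 0.083 over 5 relations) and a Pearson's r of -0.67 (exact permutation p = 0.11, adjusted p = 0.274; -0.58 without the 2 arrays farthest from the median day). With a single pooled threshold, chosen after seeing the data, these were rho = -0.52 (exact permutation p = 0.224) and r = -0.52 (exact permutation p = 0.238; 0.06 without the same 2 arrays).

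Of 19 lists, the immediate early and heat shock list alone passed against other genes, with a median slope of 0.50 log2 units per day and 8 of 9 members positive (limma camera, preset correlation 0.01, adjusted p = 0.0129). The call was lost with an estimated correlation within the list (adjusted p = 0.317 with an estimated correlation). Slopes were 1.10 ± 0.58 (SE) for the heat shock gene Hspa1a, 0.63 ± 0.59 for Fos and 0.49 ± 0.22 for Egr1, against -1.29 ± 0.56 for the chaperone gene Hsph1. Of its members, 0 passed over all genes and 0 when adjusted over the list alone, which also held for the other 18 lists. The call was also lost without array 1 (adjusted p = 0.212), without array 4 (0.235), without array 7 (0.0757) and with the share of genes above background as a covariate (0.279). The fry test of limma, which sets the list against no change rather than against other genes, gave an adjusted p = 0.291. The lung epithelium list had a median slope of -0.48 (limma camera, adjusted p = 0.42) and passed only without array 5 (median slope -0.78, adjusted p = 0.0062). It was -0.14 without array 4, -0.21 without array 1, -0.21 without array 2 and -0.24 without array 6.

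Gene groups varied widely between samples. For the placental labyrinth genes the mean pairwise Pearson correlation across the 7 arrays was 0.48, at the 100th percentile of random lists matched on mean signal. Of these genes, Ctsq, Ctsj, Ctsr, Rhox6, Rhox9 and Peg10 were highest on array 3, and Tfap2c and Ets2 on array 6. The value may thus rest largely on array 3, and it was not computed without that array. The mean pairwise correlation was 0.31 for the lung epithelium list, 0.26 for the cell cycle list and 0.21 for the housekeeping list, each above the central 95% of random lists. It was -0.20 for the trophoblast hormone list and -0.15 for the imprinted list, at percentiles 1.57 and 0.60, below that range. With the median over probe sets the imprinted list lay at 0.09 (percentile 82.33), the hormone list at -0.20 (1.91), the labyrinth list at 0.28 (99.32) and the housekeeping list at 0.36 (99.96). The alveolar macrophage list, at 0.17 before, then exceeded the central 95% (0.33, percentile 97.6). After quantile normalization the cell cycle (percentile 95.66) and housekeeping (96.75) lists no longer exceeded the central 95%. The SD of list scores between arrays, where a score is the list median minus the median of all named genes, was largest for lung epithelium (1.39), housekeeping (1.23), alveolar macrophages (1.21) and immediate early genes (1.19), and smallest for monocytes and macrophages (0.29) and trophoblast hormones (0.31). The order depended on the setting: the largest was 1.38 for immediate early genes after quantile normalization and 1.45 for housekeeping with the median over probe sets, where the erythroid list was smallest (0.20, against 0.84). Single genes above background on at least 3 arrays differed by SDs of up to 5.04, in the ubiquitin ligase gene Wwp1; Cyb5r3, Igfbp5, Idi1, Rora, Ssbp1, Tomm20, Ankrd33b, Unc45b, Prpf4b, Chd9, Ewsr1, Sf1, Klf9 and Tmem33 followed, with SDs down to 4.50.

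**Figure D3:**
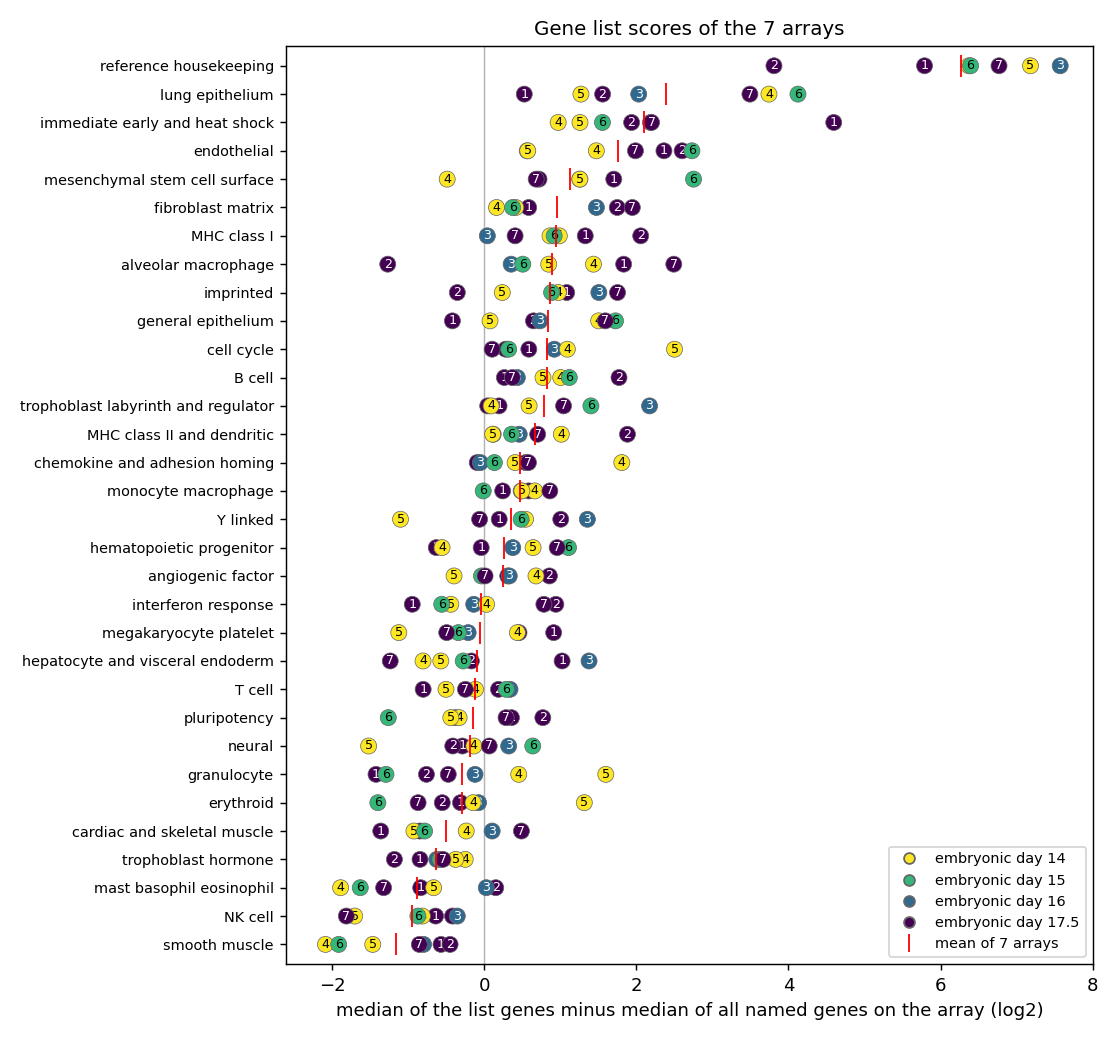
Score of each gene list (horizontal axis, log2: median of the list's genes minus the median of all named genes on the array) for the 7 arrays. Each numbered circle is 1 array, coloured by embryonic day, and the red tick is the mean of the 7. The cell cycle score of array 5 (2.5), the immediate early score of array 1 (4.60) and the chemokine and adhesion score of array 4 (1.81) stand apart from the other arrays. The immediate early score of array 1 alone also did so both after quantile normalization and with the median over probe sets.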

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

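The tests on globin genes, on Xist and on genes highest on arrays 3, 5 and 6 were chosen after the values were seen. The other tests were fixed before their results.

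An array stood far from the other 6 in 10 of 130 measures, lists and genes examined, where chance alone gives about 6.5. Among control probe sets, the beta-actin 3' signal was 3.21 on array 2 against 9.24 to 11.04 elsewhere, and the difference between 3' and 5' Gapdh signals was 6.46 on array 3 against 1.5 to 2.76. Other probe sets did not follow: the brightest Actb probe set was 12.80 on array 2. On array 3 the beta-actin control was lower at 3' (9.48) than at 5' (11.26). Among lists, the cell cycle score of array 5 was 2.5, the immediate early and heat shock score of array 1 was 4.60, and the chemokine and adhesion score of array 4 was 1.81. After quantile normalization the immediate early score stayed apart (Dixon Q 0.65), the cell cycle (0.49) and chemokine (0.40) scores did not, and the housekeeping score of array 2 newly did. With the median over probe sets the chemokine score did not (0.44) and the imprinted score of array 2 newly did (0.60). Among genes, each lowest on the array named, Egr1 was 8.84, Ahnak 10.39 and Gsn 10.26 on array 5, Malat1 was 11.36 on array 2 and Fth1 was 11.92 on array 3.

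Lung epithelial transcripts were above background on every array, although the cells were sorted for a fetal label. Red cell transcripts were taken as a sign of RNA of whole maternal lung. The 3 adult globin genes with their own probe set were above background on a mean of 4.33 arrays, between the bounds set for and against. Hbb-b2 was above on 6, Hba-a2 on 5 and Hba-a1 on 2. Fetal red cells of these ages can carry the same transcripts, so a high count could not have separated maternal blood from fetal cells. A first version of this test used Hba-a1 alone and would have argued against whole-lung RNA; it was widened once Hbb-b2 was seen. Maternal epithelial cells or their free RNA should dilute placental transcripts, yet the lung list did not fall where the trophoblast labyrinth list rose (Pearson r = 0.28, exact permutation p = 0.549, Spearman rho = 0.32, exact permutation p = 0.498, r = 0.48 without the 2 farthest arrays), which with 7 arrays decides nothing. Green sorting would remove intact maternal cells but not free RNA, so maternal RNA, misgated maternal cells and fetal cells that express lung genes all remain open, and no maternal reference is analysed here to tell them apart.

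The second pattern was that Eif2s3y, Kdm5d and Uty were above background on 0 arrays and Usp9y on 1, in a label that marks fetuses of either sex, whereas Sry was above on 5 and Zfy2 on 3. Low sensitivity at up to 80 cells is a candidate explanation: the X-linked partners Eif2s3x, Kdm5c, Kdm6a and Usp9x were above background on a mean of 2.75 arrays, against 0.25 for these 4 Y-linked genes, which lies between the bounds set for and against it. With the pooled threshold, chosen after seeing the data, the partners had a mean of 2 arrays, which meets the bound set for low sensitivity, so that explanation stays open. Few male cells, or much RNA from female cells, is also open and is consistent with Xist above background on 7 of 7 arrays, although that rests on 1 of 3 probe sets and female fetal cells express Xist too. The sex of the fetuses behind each array is not in the labels, so fetal sex as the cause was not tested.

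For some lists, many genes were highest on a single array. The lists and arrays were picked after their values were seen, which weakens these comparisons. Signals were first centred on each array's median, which removes a uniform shift in brightness, so these counts cannot test such a shift. Of 62 erythroid, granulocyte, progenitor and cell cycle genes, 27 were highest on array 5. Random sets matched on mean signal had a median of 9 and an upper 95% limit of 15. The count thus shows an excess over other genes of similar mean signal, and it was not repeated after quantile normalization. The other day 14 array held 9 of these highest values (random median 7, upper limit 12), which leaves gestational day open. Of 40 trophoblast genes, 14 were highest on array 3 (upper limit 13), which is 1 over a limit that does not allow for the choice of list and array and so decides little. The 3 of 12 NK cell genes highest on array 6 lay within the random range (upper limit 4). By list, array 5 held 6 of 13 erythroid (upper limit 4), 8 of 15 granulocyte (5) and 9 of 19 cell cycle genes (6), and 4 of 15 progenitor genes, within the random range (5). A different mixture of few cells is a hypothesis that may apply to array 5 and was not tested.

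Chance could not be excluded for the genes with an unadjusted p under 0.05 in the trend with embryonic day. Of 100 assignments of the days to the arrays, 37 gave as many as the real 214, and the highest of the others gave 544. With adjusted p-values the real assignment gave 0 genes and 6 assignments gave some, up to 12. With the days in 2 classes, 8 of the 35 splits gave as many as the real 251 genes at an unadjusted p under 0.05, and the highest of the others gave 488.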

How the results depend on the processing

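The 90th percentile and the pooled thresholds were chosen after seeing the data. Counts above background depended on the threshold; genes below it are not shown to be silent. On all arrays, on all but at most 1, and on at least 3, the counts of 117, 427 and 4020 became 57, 124 and 1045 at the 99th percentile, 520, 1285 and 6254 at the 90th, 5373, 9024 and 15446 above the 40th percentile of all probe sets, 40, 156 and 1911 with the median over probe sets, and 241, 561 and 2870 with the pooled threshold. Leaving out each array in turn gave 120 to 348, 455 to 1123 and 2676 to 3979; the high ends came without array 1, whose threshold was highest, the 829 genes on all but at most 1 array came without array 7, and the 2676 without array 5. The lists above the receptor genes numbered 26 with the median over probe sets (NK cell, hepatocyte, pluripotency and neural lost, granulocyte gained, and 11 differences over 1.5 times smaller), 29 after quantile normalization and 23 to 25 with an array left out. In the trend with embryonic day, limma gave 0 genes under all 17 alternatives; genes at an unadjusted p under 0.05 numbered 992 without a filter, 3 among genes above background on all 7 arrays, 363 with array weights, 133 with the pooled filter and 162 to 354 with an array left out (354 without array 7), where all of these but the array weights and the left-out arrays tested another number of genes. Lists passing numbered 0 with an estimated correlation, 0 with the covariate and 0 to 2 with an array left out. For the immediate early and heat shock list, the median slope was 0.50 with an estimated correlation (adjusted p = 0.317), 0.34 with the covariate (adjusted p = 0.279) and 0.35 to 0.59 with an array left out (adjusted p from 0.0062 to 0.235); it passed after quantile normalization, with 2 classes of days and with the pooled filter. Lists whose genes vary together numbered 2 after quantile normalization instead of 4. Except where fewer genes or arrays explain it, the cause was not tested. For single lists against the receptor genes, 40 of 288 alternative values no longer passed and 1 newly passed, all in the same direction; of these 36 left out an array, where the smallest possible p is larger. All 150 alternative slopes of the 10 named trend genes kept their sign and none passed. With signals floored at the threshold they were much smaller (-0.26 to -1.02), but that floor was highest on arrays 1 and 7, both E17.5. SDs of list scores moved with the median over probe sets: erythroid from 0.84 to 0.20, mesenchymal stem cell surface from 1.00 to 0.34, MHC class II from 0.63 to 0.29, endothelial from 0.91 to 0.50, chemokine from 0.65 to 0.36, imprinted from 0.72 to 0.45 and monocytes from 0.29 to 0.51. With the pooled threshold the list members on at least 6 arrays numbered 2 endothelial instead of 0, 3 MHC class I instead of 1, 2 MHC class II instead of 1, 1 cell cycle instead of 0, 0 general epithelium instead of 1, 5 lung epithelium instead of 7, 3 trophoblast hormone, 3 monocyte and 3 fibroblast instead of 2 each, 2 imprinted instead of 1 and 3 immediate early instead of 4. No paired analysis was possible because the samples form a single group.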

Other observations

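All genes, the correlation and the test of ribosomal protein genes given here were chosen after the values were seen.

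Array 5, a day 14 sample, held high signals for some genes of granulocyte precursors and of dividing cells. The myeloperoxidase gene Mpo was 11.70 there and at most 5.56 on the other arrays, the proteinase gene Prtn3 was 9.77 and at most 5.22 elsewhere, and the transferrin receptor gene Tfrc was 10.91 and at most 5.49 elsewhere. The proliferation marker Mki67 was 10.70, the replication gene Mcm6 11.52 (from a probe set type that can hybridise to related sequences) and the calprotectin gene S100a8 10.44. Others were low there: Elane was 4.77 and not above background, Cdk1 3.52, Plk1 3.26, Aurka 4.20 and Mcm2 3.32. Genes of the erythroid list were highest on array 5 in 6 of 13 cases, of the granulocyte list in 8 of 15, of the progenitor list in 4 of 15, within the range of random genes, and of the cell cycle list in 9 of 19. Across the 7 arrays the erythroid and cell cycle scores were correlated (Pearson r = 0.93, exact permutation p = 0.0079, adjusted p = 0.0397 over 5 relations; Spearman rho = 0.86, exact permutation p = 0.0238, adjusted p = 0.0833), and r was 0.94 without the 2 farthest arrays. Only 2 of the 13 erythroid genes were above background on at least 3 arrays, so the erythroid score rests largely on signals below background. Its SD between arrays fell from 0.84 to 0.20 with the median over probe sets, and the correlation was not computed in that setting. The globin genes did not follow the array 5 pattern: Hbb-b2 was highest on arrays 4 (13.15) and 6 (12.42) and was 8.83 on array 5, the embryonic globin gene Hbb-y was above background on 0 arrays and Hbb-bh1 on 3 (7.64 on array 2, 5.68 on array 3 and 5.33 on array 5), and the heme synthesis gene Alas2 was above on array 4 only (8.91).

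Array 3, the day 16 sample, held the highest signals of some placental genes and the lowest of others. Its 3' Gapdh signal exceeded the 5' one by 6.46, whereas its beta-actin control was lower at 3' (9.48) than at 5' (11.26). The placental cathepsin gene Ctsj was 13.39, the prolactin family genes Prl2b1 and Prl7d1 were 13.06 and 11.54, and the homeobox gene Rhox6 was 11.93. The pregnancy-specific glycoprotein genes Psg23 (4.19) and Psg28 (6.40) were lowest there. The epithelial adhesion gene Epcam was 10.73 on this array and at most 6.27 on the others. The cytotoxic granule gene Gzma was above background on arrays 4 (9.79) and 6 (11.25), as was the chemokine gene Ccl5 (7.20 and 9.72), and the NK receptor gene Klra8 was 9.02 on array 6 and at most 2.68 on the others. The only Klra8 probe set is of the type that can hybridise to related sequences.

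Among single genes, picked for their high values, the chemokine gene Cxcl15 averaged 11.32 ± 2.08 and was above background on 6 of 7 arrays, the hypoxia factor gene Epas1 averaged 11.80 ± 1.55 (7 of 7), Inmt 8.77 ± 1.01 (6 of 7) and the endothelial receptor gene Calcrl 9.64 ± 1.04 (7 of 7). Igha, the constant region of immunoglobulin A, averaged 10.78 ± 1.43 and was above on 7 of 7 arrays in its brightest of 3 probe sets, whereas the joining chain gene Jchain was above on 0.

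Ribosomal protein genes with their own probe set made up 17 of the 117 genes above background on all 7 arrays. They were 46 of the 18194 named genes, so 37.0% of them were above on every array against 0.643% of all genes (Fisher's exact test, two-sided, across genes, which are not independent replicates, p = 2.46e-26).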
